A study of Homo sapiens with 9 samples.

How the data were processed

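RNA of U87 cells was hybridised to Affymetrix human expression arrays, with 1 array per sample. Per the labels' protocols, 100000 cells were transfected for 24 h with 50 nM of a miRNA duplex by a lipid reagent, RNA was purified on columns after Trizol extraction, and 1 µg of total RNA was labelled with biotin-ULS. The deposited values are linear probe-set signal intensities, with 1 value per probe set and array. GCOS 1.4.0.036 is named per the submitters' processing notes, while its role, the signal algorithm and the scaling target are not given in the sources used here. In the deposited values each array had a 2% trimmed mean signal between 100.009 and 100.011, so the arrays already shared a scale. All values were above 0, and no pair of arrays was identical. Scaling to a trimmed mean fixes the average of each array, so a shift of all transcripts together cannot be seen in these values.

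The labels give 3 groups (miR-376a*A, miR-376a*G and control miRNA) of 3 biological replicates. The comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except for 1 alternative and the tests, gene families and genes that are said to be chosen after the result or values were seen. Of 54675 probe sets, 62 array controls were left out, 41091 had a single gene symbol in the platform annotation used here, 1801 had several and 11721 had none. They held 19775 distinct symbols. Symbols were compared through Entrez identifiers with a RefSeq gene table for GRCh38.p14, which was used for names only. No symbol was changed by it, and 54 named probe sets had an identifier outside that table. Of the 627 symbols in the 26 fixed gene lists, 563 were matched to the array.

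Signals were analysed as log2(signal + 16) without further scaling. Fold values are therefore on the log2(signal + 16) scale and understate the change of dim genes. Probe sets with a mean log2 value at or above the 40th percentile (4.771, a signal of 11.3) were kept, 32768 in all. Each gene was represented by its probe set with the highest mean, and probe sets without a single symbol were tested as they were. This gave 20068 features, 13697 of them with a single symbol. Where a called gene had other tested probe sets, their directions were compared. Of 3067 called single-symbol genes for miR-376a*A against control 1860 had another tested probe set. In 1282 all others had the same sign, in 927 another passed in the same direction, and in 71 another passed in the opposite direction. The counts were 3896, 2340, 1653, 1274 and 97 for miR-376a*G against control and 2814, 1680, 1276, 871 and 25 between the forms. Genes named in the text that passed were more even, with 31 of 35, 34 of 37 and 23 of 28 such genes of one sign and 0 opposite calls. These counts leave out RAP2A with miR-376a*G, which did not pass while 2 of its other probe sets passed as lower.

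Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with an intensity trend) on all 9 arrays, with 6 residual and 6.48 prior degrees of freedom. Tests were two-sided, and a feature passed at a Benjamini-Hochberg adjusted p under 0.05. The 3 comparisons were each form against control and the forms against each other. Gene lists with at least 5 tested genes (24 lists) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Adjusted p-values of lists in the text are those of camera. The 12 largest rises and falls per comparison were named among single-symbol genes that passed and whose groups did not overlap, with up to 4 members of smallest p from each list, RAP2A, ADAR and ADARB1. A further gene that the rule names is not reported here. Others are described as chosen after their values were seen. Because both forms share the control arrays, the overlap of their calls was compared with 100 simulated draws of unchanged groups sharing a simulated control. All 9 arrays of a draw, the controls included, varied independently around the control mean with the pooled spread of each feature. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

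The test was tried on simulated data for 20068 features, 200 of them changed. In the simulation of miR-376a*A against control 87% of the 1.5-fold and 100% of the 2-fold changes were recovered, with 5.56% false calls. The values were 82%, 98% and 4.76% for miR-376a*G against control, and 85%, 100% and 4.15% between the forms. In the first of these simulations 1 unchanged list was also called. Simulated features varied independently, with the pooled spread of each feature on all 9 arrays. The real data had uneven control arrays, correlated genes in some lists and many more calls, so these rates need not hold for them. Alternatives covered the scaling between arrays, the filter, the offset, the variance model, array weights, the probe set rule, the arrays in the fit, the replicate number as a block, the thresholds, the list test and each replicate left out in turn. A planned comparison of genes with seed sites in their 3' untranslated regions was not run, since no transcript sequences were used here. The 3'/5' signal ratio was between 0.866 and 0.907 for GAPDH and between 0.868 and 0.908 for ACTB over the 9 arrays.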

Results

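Gene expression was measured on 9 Affymetrix human expression arrays of U87 cells, an established human glioma line. Cells were transfected with a miRNA duplex at 50 nM and harvested after 24 h. The duplex was miR-376a*A, miR-376a*G or a control miRNA, and each was represented by 3 biological replicates. In published work on this miRNA the A form is the unedited sequence, and the G form carries the base that A-to-I RNA editing leaves, which is read as G. Each array was scaled to the same trimmed mean signal of 100.01, with median signals between 18.0 and 20.4 and highest signals between 3335 and 4115. Across genes, which are not independent replicates, arrays of one group correlated with r between 0.9865 and 0.9952. The lowest of these values was that of control replicates 1 and 2. The SD of the deviations from the group mean was 0.164, 0.145 and 0.113 (log2) on control replicates 1, 2 and 3, and between 0.102 and 0.114 on the 6 miR-376a* arrays. Replicate number limits the precision. The median SE of a log2 difference between 2 groups was 0.101 over the 20068 features tested, of which 13697 were genes with a single symbol.

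The first comparison asked which genes differed after transfection of the unedited form. With miR-376a*A, 4177 features passed the test against the control (2164 higher, 2013 lower), and 184 of them differed at least 2-fold (71 higher, 113 lower). The genes with the largest falls included BRI3BP (5.44-fold lower), the RAS-family GTPase gene RRAS2 (4.97-fold lower), COMMD2 (4.69-fold lower), the fatty acid elongase gene ELOVL5 (4.57-fold lower) and VMA21, which encodes an assembly factor of the vacuolar proton pump (4.41-fold lower). SKP2, the substrate-recognition subunit of an SCF ubiquitin ligase, fell 4.27-fold, from a signal of 496.6 ± 79.8 (SD, n = 3) in the control to 103.4 ± 9.5 (SD, n = 3). TWSG1, TVP23B, ATE1, TOR1B, YRDC and the long non-coding transcript STX17-DT completed the 12 largest falls, at 3.54-fold to 4.24-fold. STX17-DT was the least precise of them, with a log2 difference of -1.82 ± 0.295 (SE). The largest rises were those of the nucleoporin gene NUP37 (4.62-fold higher, adjusted p = 1.12e-09), the atlastin gene ATL3 (4.59-fold), GALNT1, which starts mucin-type O-glycosylation (4.27-fold), and the glyoxalase gene GLO1 (3.93-fold). PODXL, MRPS14, WDFY1, LAMTOR3, MTMR6, the N-cadherin gene CDH2, the nuclear receptor gene NR1D2 and the cytokine gene IL11 rose 3.45-fold to 3.81-fold. Of these 12 largest rises, all except IL11 were also at least 2-fold higher with miR-376a*G than in the control. The falls of ELOVL5 and VMA21 and the rise of ATL3 each rest on 1 probe set, since other tested probe sets of these genes gave -0.33 to 0.07, -0.23, and 0.12 to 0.25 (log2) and did not pass. Over all features tested, the 3 arrays of one group lay apart from the 3 of the other in 36.7%, against 10% by chance.

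RAP2A, a RAP-family GTPase gene that published work on these miRNAs names as a target of the A form, fell 1.56-fold with miR-376a*A. Its signal was 565.6 ± 45.5 (SD, n = 3) against 891.3 ± 98.0 (SD, n = 3) in the control, a log2 difference of -0.64 ± 0.084 (SE, adjusted p = 0.000177). As the study may have chosen RAP2A on these samples, its direction is not independent evidence. A second bright probe set of the gene gave -0.78 ± 0.065 (SE), and a pair of dim ones gave -0.26 ± 0.08 and -0.26 ± 0.113 (SE). Among 22 tested RAP and RAS pathway genes, 3 rose and 6 fell, the same 3 and 6 adjusted over the list alone, and the list was not called (camera adjusted p = 0.568). RAP2B and RAP1B rose 1.52-fold and 1.48-fold. ADAR, which encodes an adenosine deaminase that edits double-stranded RNA, fell by 0.26 ± 0.074 (SE) on the log2 scale (adjusted p = 0.0269). That call ended without any one of the 3 miR-376a*A arrays or without control replicate 2, with adjusted p between 0.0526 and 0.101. ADARB1, the gene of a related deaminase, stood at -0.11 ± 0.122 (SE), which did not pass.

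Genes induced by p53 rose as a group with miR-376a*A. Of 24 tested members 12 rose, 2 fell (XPC and ZMAT3, named after their values were seen) and 10 did not pass, with a list median of 0.28 (log2) and a camera adjusted p of 0.00328. The list had an adjusted p of 0.2 with an estimated correlation, and adjusted over the list alone 13 rose and 2 fell. The XPC call ended without miR-376a*A replicate 1 or 2 or control replicate 3 and the ZMAT3 call without miR-376a*A replicate 2 or 3, with adjusted p between 0.0574 and 0.0835. TIGAR, a regulator of glycolysis and oxidative stress, rose 1.58-fold, the death receptor gene FAS 1.4-fold, TP53INP1 1.74-fold and SESN1 1.38-fold. Interferon-stimulated genes were lower: 7 of 24 fell and 0 rose, the same counts adjusted over the list alone, with a median of -0.14 and an adjusted p of 0.0134. This list had an adjusted p of 0.2 with an estimated correlation, of 0.0513 after quantile normalization and of 0.0511 without miR-376a*A replicate 1, and 4 of its genes fell without miR-376a*A replicate 3. IFIT3, HERC6, HERC5 and SAMD9 fell 1.52-fold, 1.5-fold, 1.47-fold and 1.4-fold, although another tested probe set of IFIT3 gave -0.20 and did not pass. None of the 26 tested cytosolic ribosomal protein genes passed singly, over all genes or adjusted over the list alone, although the list was called as higher (median 0.13, adjusted p = 0.0134). It had an adjusted p of 0.915 with an estimated correlation and of 0.651 after quantile normalization, where the median was 0.03. The ribosomal call also ended without miR-376a*A replicate 1, control replicate 1 or control replicate 3, with adjusted p of 0.184, 0.246 and 0.0563, whereas 10 of the 26 genes rose without control replicate 2.

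Other fixed lists moved in both directions with miR-376a*A and were not called. Among 19 NF-kB and inflammatory cytokine genes 7 rose and 1 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.395), with IL11, IL6 and CXCL3 at 3.45-fold, 2.32-fold and 2.12-fold. In the list of 28 TGF-beta target and extracellular matrix genes 11 rose and 6 fell (12 and 6 adjusted over the list alone, adjusted p = 0.377). The lysyl oxidase gene LOXL2 rose 1.62-fold and the collagen gene COL6A2 fell 2.11-fold, each on 1 probe set only. The other tested probe sets gave 0.07 and 0.17 (log2) for LOXL2 and 0.12 for COL6A2 and did not pass. Among 23 unfolded protein response and ATF4 target genes 6 rose and 3 fell (7 and 3 adjusted over the list alone, adjusted p = 0.568), and the cystine transporter gene SLC7A11 fell 2.07-fold. Among 33 G2/M and mitosis genes 7 rose and 5 fell (9 and 6 adjusted over the list alone, median 0.06, adjusted p = 0.684). In that list 13 rose without control replicate 2, and 2 fell without miR-376a*A replicate 1 or 3. Its genes CCNA2, NEK2, TOP2A and CENPA rose by 1.15, 0.75, 0.51 and 0.35 (log2), the last with an adjusted p of 0.0652 without miR-376a*A replicate 3. Centring each array on its own median turned the split of calls for miR-376a*A to 1660 higher and 2354 lower. The smallest differences therefore have no firm direction, since the median over all features was 0.041 (log2) before and 0.003 after that centring.

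**Figure D1:**
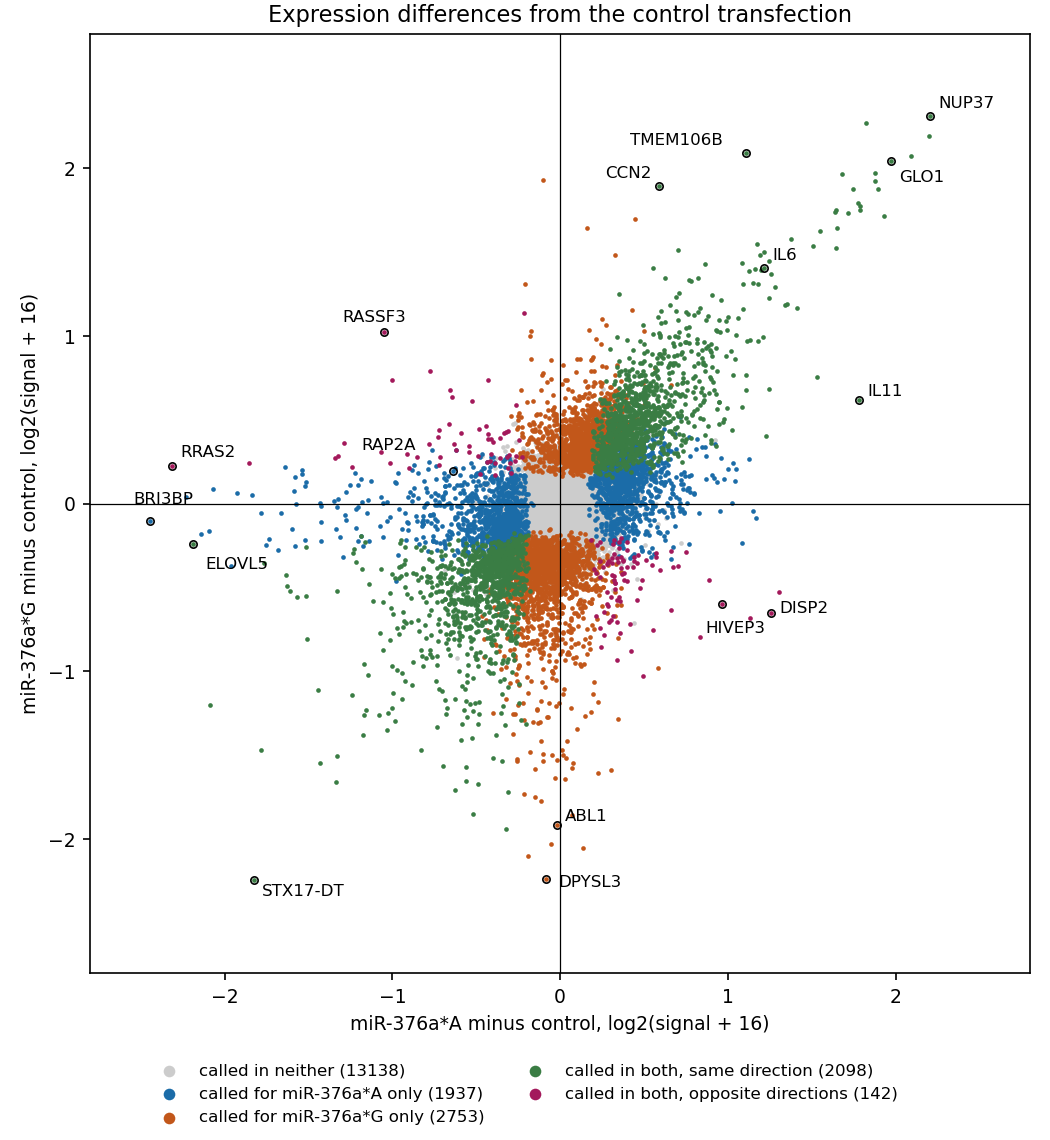
Each point is 1 of the 20068 tested features, placed by its log2 difference in signal (offset 16) from the control transfection with miR-376a*A (horizontal axis) and with miR-376a*G (vertical axis), each from 3 arrays per group. Colours mark the 1937 features called for miR-376a*A only, the 2753 called for miR-376a*G only, the 2098 called in both with the same direction and the 142 called in opposite directions, and circled genes are named.

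The second comparison asked the same of the edited form. With miR-376a*G, 4993 features passed (2374 higher, 2619 lower), and 244 differed at least 2-fold (100 higher, 144 lower). The balance of all calls turned to 2592 higher and 2310 lower when each array was centred on its own median, and to 2588 and 2408 after quantile normalization. STX17-DT (4.73-fold), DPYSL3 (4.71-fold), the BMP receptor gene ACVR1 (4.29-fold), the zinc transporter gene SLC30A6 (4.08-fold) and the tyrosine kinase gene ABL1 (3.77-fold) showed the largest falls. ABL1 signal was 161.2 ± 6.6 (SD, n = 3) against 653.9 ± 65.2 (SD, n = 3) in the control. KIRREL1, the neuronal growth cone gene GAP43, WBP1L, CYB5R4, C10orf90, the histone deacetylase gene HDAC4 and AP3M1 fell 3.27-fold to 3.62-fold. NUP37 (4.95-fold), MTMR6 (4.83-fold), ATL3 (4.57-fold) and the lysosomal membrane gene TMEM106B (4.26-fold) rose most. They were followed by GALNT1, GLO1, WDFY1, the calcium channel subunit gene CACNA2D1, PLPPR4, LAMTOR3, the matricellular gene CCN2 and MRPS14, at 3.67-fold to 4.21-fold. Of these largest rises, all except PLPPR4 and CCN2 were also at least 2-fold higher with miR-376a*A than in the control. The changes of KIRREL1, C10orf90, NUP37 and CACNA2D1 each rest on 1 probe set, as another tested probe set gave -0.31, 0.04, 0.25 and 0.24 (log2) and did not pass. The size of the ATL3 rise also rests on 1 probe set, as 2 others gave 0.19 and 0.26, of which 1 passed. The groups did not overlap in 38.3% of all features, against 10% by chance. RAP2A stood at 0.20 ± 0.084 (SE) and did not pass (adjusted p = 0.107). It passed without control replicate 1, at 0.28 with an adjusted p of 0.0135, and with array weights, at 0.33 with an adjusted p of 0.000216. The array weights did not converge and favoured control replicate 3 (8.156, against 0.189 for control replicate 1), so the weighted value says little. The second bright probe set of RAP2A gave 0.02 ± 0.065 (SE). The dim pair gave -0.35 ± 0.08 and -0.33 ± 0.113 (SE) and passed as lower, so the probe sets of this gene did not share a direction here. ADAR fell 1.42-fold (adjusted p = 0.000332), and ADARB1 stood at -0.22 ± 0.122 (SE, adjusted p = 0.206), with another, dimmer probe set at -0.48 ± 0.125 (SE). With the mean of its probe sets ADARB1 passed, at -0.26 with an adjusted p of 0.0425.

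Genes of G2/M and mitosis were higher with miR-376a*G. Of 33 tested members 21 rose, 0 fell and 12 did not pass (23 rose and 0 fell adjusted over the list alone), with a median of 0.27 (log2). Without miR-376a*G replicate 2, 13 rose. The cyclin gene CCNA2 rose 2.49-fold, the mitotic kinase gene NEK2 1.95-fold, the centromere histone gene CENPA 1.8-fold and the topoisomerase gene TOP2A 1.56-fold. All 4 also passed as higher with miR-376a*A. The camera adjusted p was 4.34e-10, and this was the only list of the comparison whose call held with an estimated correlation (adjusted p = 0.0228). Replication-dependent histone genes were also called as higher: 7 of 10 rose and 1, H2BC21, fell, the same counts adjusted over the list alone, with a median of 0.46 and an adjusted p of 0.0115. That p was 0.479 with an estimated correlation. The list's mean deviation from the average of all arrays was uneven in the control, at -0.32, -0.11 and -0.02 (log2) on replicates 1, 2 and 3. With miR-376a*G it was 0.20, 0.21 and 0.22. Among G1/S and DNA replication genes 8 of 36 rose and 2 fell, the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.102). In that list 5 rose without miR-376a*G replicate 3 and 13 without control replicate 1.

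Inflammatory cytokine genes rose with miR-376a*G. Of 19 tested NF-kB and cytokine genes 13 rose, 0 fell and 6 did not pass (13 rose and 2 fell adjusted over the list alone), with a median of 0.52 and a camera adjusted p of 7.14e-08. The adjusted p was 0.153 with an estimated correlation. The chemokine genes CCL2 and CXCL1 rose 2.8-fold and 2.38-fold, IL6 2.65-fold and the cytokine gene LIF 2-fold. Interferon-stimulated genes went the other way, with 9 of 24 lower and 2 higher (11 and 2 adjusted over the list alone, median -0.18, adjusted p = 0.032). This list had an adjusted p of 0.155 with an estimated correlation, of 0.0593 after quantile normalization and of 0.0615 without miR-376a*G replicate 1, and 6 of its genes fell without miR-376a*G replicate 2. IFIT3 and PARP9 fell 1.7-fold and 1.47-fold, whereas IFI44L rose 1.36-fold. Another tested probe set of PARP9 gave -0.08 (log2) and did not pass.

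Integrin and focal adhesion genes and hypoxia and glycolysis genes were lower with miR-376a*G. Among 27 tested integrin and focal adhesion genes 14 fell, 1 (PARVA, named after its values were seen) rose and 12 did not pass, with 15 lower and 1 higher adjusted over the list alone. The list median was -0.29 and its adjusted p 8.12e-06, or 0.155 with an estimated correlation. None of the 6 other tested probe sets of PARVA passed, and its call ended without miR-376a*G replicate 2 or 3 or control replicate 3, and with the mean of its probe sets, with adjusted p between 0.0518 and 0.143. The integrin genes ITGB3 and ITGA5 fell 2.96-fold and 2.32-fold, the vinculin gene VCL 2.09-fold and the kindlin gene FERMT2 1.6-fold. Hypoxia and glycolysis genes fell in 15 of 28 cases and rose in 0 (17 and 0 adjusted over the list alone), with a median of -0.24 and an adjusted p of 2.47e-07. The adjusted p of this list was 0.307 with an estimated correlation. PFKFB4, which controls a key activator of glycolysis, fell 1.94-fold, NDRG1 1.86-fold, the glucose transporter gene SLC2A1 1.5-fold and the enolase gene ENO2 1.48-fold. Several lists that were not called held large single changes: the matrix protease genes ADAMTS1 and ADAMTS5 rose 2.65-fold and 2.48-fold, the lysosomal protease gene CTSD fell 1.99-fold, CCN2 and CCN1 rose 3.71-fold and 2.04-fold, and the stress-response transcription factor gene DDIT3 rose 2.15-fold. In the p53 target list 8 of 24 rose and 7 fell (10 and 8 adjusted over the list alone, adjusted p = 0.798). There 5 rose without miR-376a*G replicate 3 or control replicate 3, and 4 fell without miR-376a*G replicate 2. The death receptor gene TNFRSF10B fell 2.32-fold and MDM2, the ubiquitin ligase gene that limits p53, rose 1.6-fold. Only 3 of 6 other tested probe sets of MDM2 shared its sign. They ranged from -0.33 to 1.06 (log2), and 2 passed as higher and 0 as lower.

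**Figure D2:**
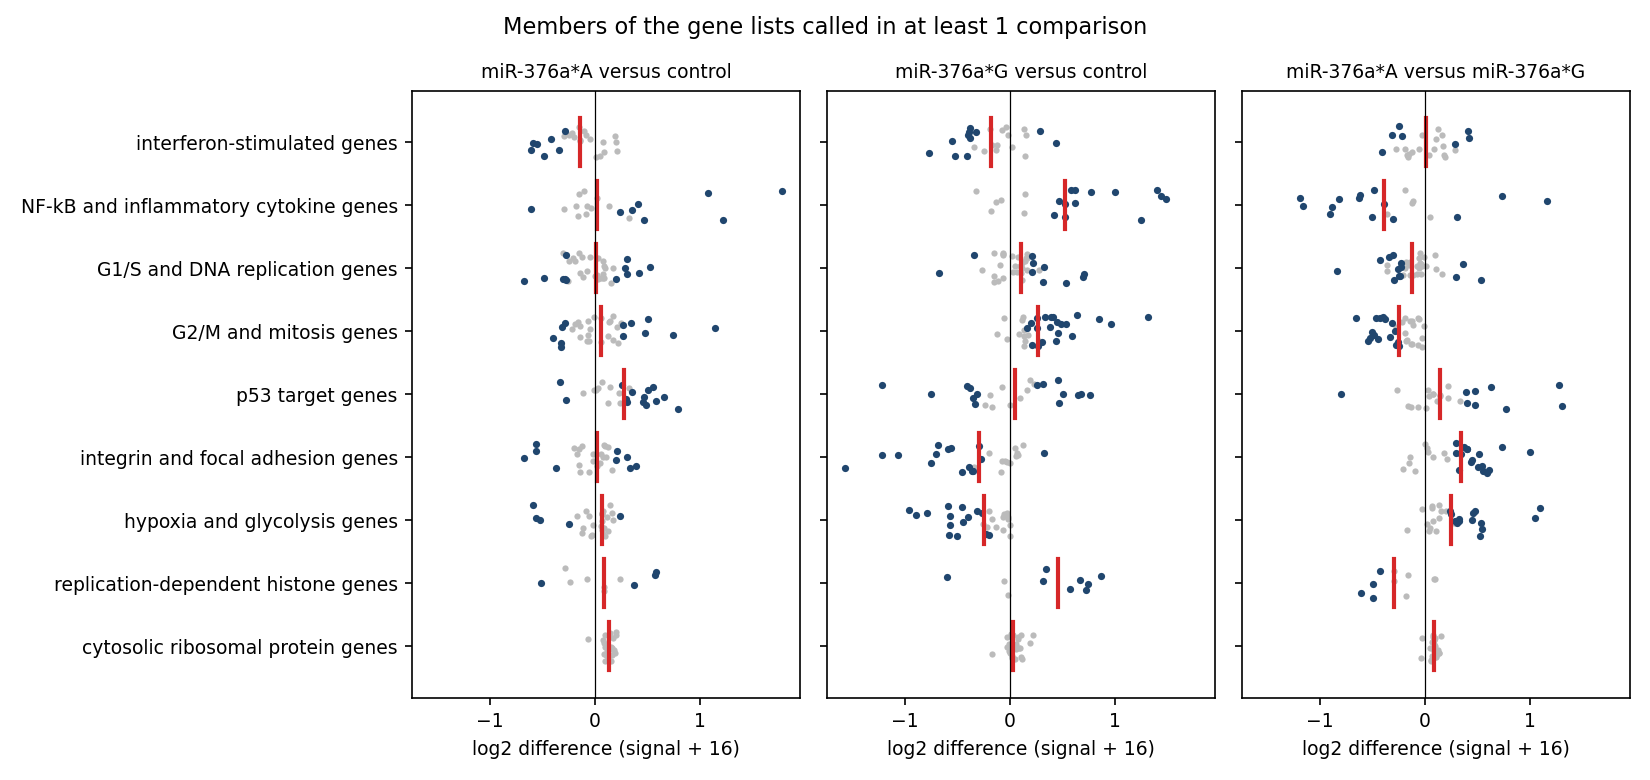
Log2 difference in signal (offset 16) of each tested member of the 9 lists called in at least 1 comparison, with 1 panel per comparison. Dark points passed the test, grey points did not, and red bars are list medians (0.27 for G2/M genes and -0.29 for integrin and focal adhesion genes in the middle panel).

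The forms were then compared with each other, which tests the difference itself, while the control arrays enter the shared estimate of the spread. Between miR-376a*A and miR-376a*G, 3671 features passed (2086 higher with miR-376a*A, 1585 lower), and 200 differed at least 2-fold (102 higher, 98 lower). Centring each array on its own median turned this split to 1509 higher and 2217 lower, and 2441 and 2331 features passed without miR-376a*A replicate 2 or miR-376a*G replicate 2. With the control arrays left out of the fit 5472 passed. In fits of only the 2 groups compared, 3191 passed for miR-376a*A and 4021 for miR-376a*G against the control. The order of the 3 comparisons by count therefore depends on the shared estimate of the spread. RRAS2 (5.82-fold), BRI3BP (5.08-fold), COMMD2 (4.83-fold), TVP23B (4.46-fold) and RASSF3 (4.21-fold) were lower with miR-376a*A, followed by PLPPR4, TOR1B, VMA21, ELOVL5, SKP2, YRDC and the zinc importer gene SLC39A10 at 3.63-fold to 4.09-fold. DPYSL3 (4.45-fold), SLC30A6 (3.94-fold), KIRREL1 (3.8-fold), ACVR1 (3.75-fold) and ABL1 (3.72-fold) were higher with miR-376a*A. CDC26, UBP1, PTPRG, WBP1L, DEPP1 and RIDA were higher by 3.08-fold to 3.7-fold. DISP2 was higher too, but its signal with miR-376a*G was 3.1, under the filter's 11.3, so its fold depends on the offset and is not given. The differences of VMA21, ELOVL5, KIRREL1 and DEPP1 each rest on 1 probe set, as their other tested probe sets gave 0.15, -0.02 to 0.08, 0.17 and 0.20 (log2) and did not pass. The groups did not overlap in 42.2% of all features, against 10% by chance. RAP2A was 1.79-fold lower with miR-376a*A than with miR-376a*G (log2 difference -0.84 ± 0.084, SE, adjusted p = 1.78e-05). Its second bright probe set gave -0.80 ± 0.065 (SE), but the dim pair gave 0.09 ± 0.08 and 0.07 ± 0.113 (SE). ADAR differed by 0.25 ± 0.074 (SE, adjusted p = 0.0367), a call that ended without any one of the 6 arrays compared, with adjusted p between 0.0642 and 0.137, and after median centring (adjusted p = 0.107). ADARB1 stood at 0.12 ± 0.122 (SE) and did not pass.

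G2/M and mitosis genes were lower with miR-376a*A than with miR-376a*G in 16 of 33 cases and higher in 0 (21 and 0 adjusted over the list alone), with a median of -0.24. HMMR, CENPA, KIF2C and the cyclin-dependent kinase gene CDK1 were 1.44-fold, 1.41-fold, 1.36-fold and 1.32-fold lower, whereas CCNA2, NEK2 and TOP2A did not pass (adjusted p = 0.0879, 0.173 and 0.182). With the mean of their probe sets CCNA2 and NEK2 did pass as lower (adjusted p = 0.00485 and 0.0256), as did CCNA2 after median centring (adjusted p = 0.0264). With array weights, whose estimation did not converge, CCNA2, NEK2 and TOP2A all passed as lower (adjusted p = 0.0161, 0.0203 and 0.0418). The camera adjusted p was 6.41e-11, and only this list kept its call with an estimated correlation (adjusted p = 0.0185). Among 36 G1/S genes 10 were lower and 3 higher (12 and 4 adjusted over the list alone, median -0.12, adjusted p = 0.0017). CCNE2, a cyclin gene of S-phase entry, was 1.78-fold lower, and the list had an adjusted p of 0.121 with an estimated correlation. Leaving out any one of the 6 arrays compared left between 3 and 6 G1/S genes lower, with 3 without miR-376a*G replicate 2 or 3. Of 10 histone genes 4 were lower and 0 higher (6 and 0 adjusted over the list alone, median -0.29, adjusted p = 0.00661), with an adjusted p of 0.393 with an estimated correlation and 2 lower without miR-376a*G replicate 2. The cytokine list was lower with miR-376a*A, with 11 of 19 genes lower and 3 higher (12 and 3 adjusted over the list alone, median -0.38, adjusted p = 3.48e-06). That list had an adjusted p of 0.14 with an estimated correlation. LIF and CXCL1 were 2.27-fold and 1.87-fold lower, whereas IL11 was 2.25-fold higher. Interferon-stimulated genes, called as lower with each form than in the control, were not called between the forms (median 0.01, camera adjusted p = 0.761). Of 24 such genes 3 were higher and 4 lower with miR-376a*A, the same counts adjusted over the list alone.

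Integrin and focal adhesion genes were higher with miR-376a*A than with miR-376a*G in 17 of 27 cases and lower in 0, also adjusted over the list alone (median 0.35, adjusted p = 1.09e-06, and adjusted p = 0.121 with an estimated correlation). ITGB3, LPP, the caveolin gene CAV1 and ITGB1 were 2.01-fold, 1.67-fold, 1.51-fold and 1.43-fold higher. Hypoxia and glycolysis genes were higher in 14 of 28 cases and lower in 0, also adjusted over the list alone (median 0.25, adjusted p = 3.48e-06), with NDRG1 at 2.08-fold and PFKFB4 at 2.14-fold, whose other tested probe set gave 0.46 (log2) and did not pass. That list had an adjusted p of 0.36 with an estimated correlation, and 9 of its genes were higher without miR-376a*A replicate 2, without miR-376a*G replicate 2 or after median centring. Of 24 p53 targets 8 were higher and 1, MDM2, was lower (9 and 1 adjusted over the list alone, median 0.14, adjusted p = 0.00838). The ribonucleotide reductase gene RRM2B, TNFRSF10B and SESN1 were 2.47-fold, 2.43-fold and 1.71-fold higher, and this list had an adjusted p of 0.193 with an estimated correlation. Genes of invasion and matrix proteolysis moved in both directions and the list was not called (adjusted p = 0.28). ADAMTS5 was 2.86-fold lower with miR-376a*A, and TIMP3, an inhibitor of matrix proteases, was 2.11-fold higher.

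**Figure D3:**
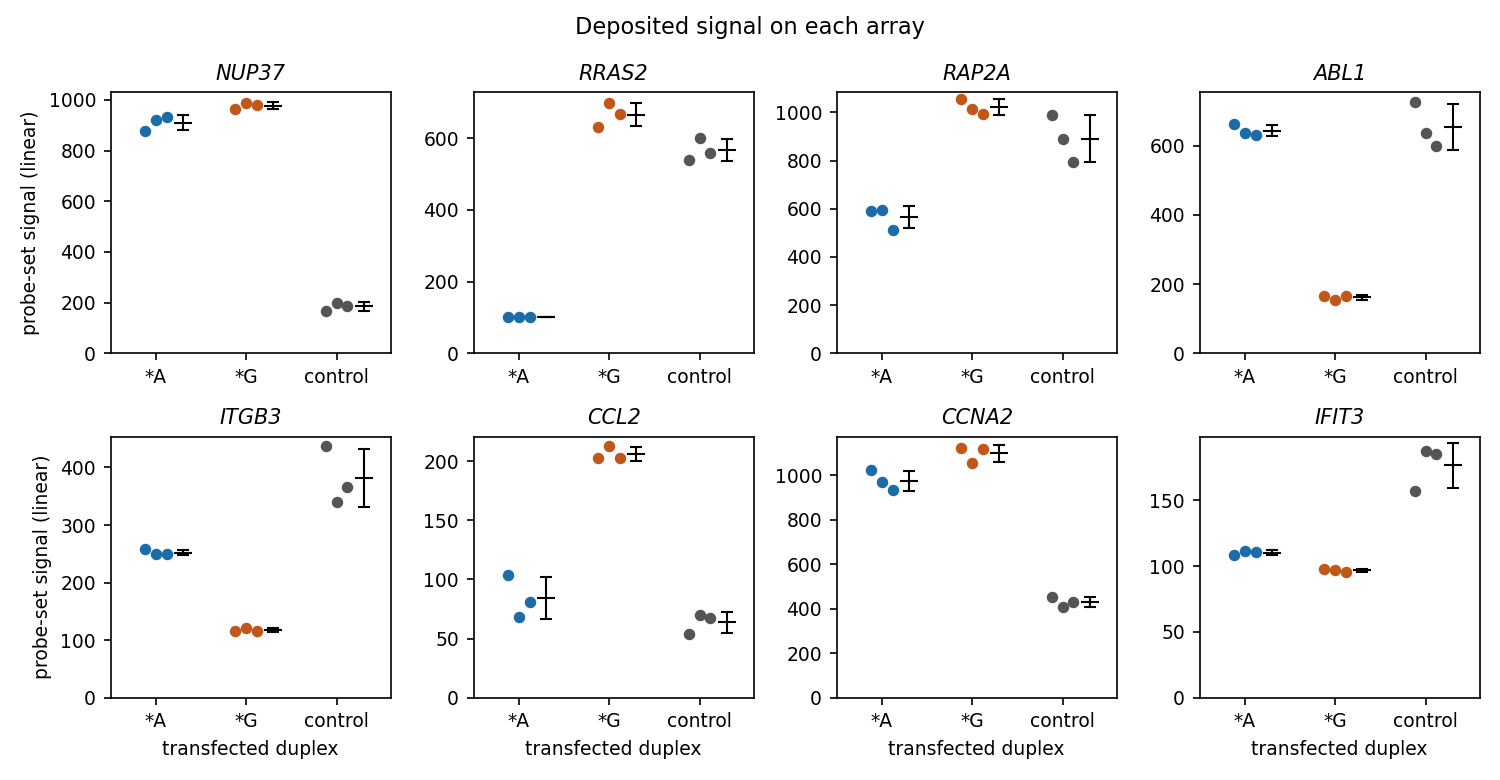
Deposited linear probe-set signal of 8 genes on each of the 9 arrays, 3 per transfected duplex (*A and *G are the forms of miR-376a*), with the mean and SD beside the points and each vertical axis starting at 0. NUP37 was lowest in the control, RRAS2 and RAP2A were lowest with miR-376a*A, and ABL1 and ITGB3 were lowest with miR-376a*G.

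Both forms were compared with the same 3 control arrays, and their changes overlapped. In both comparisons 2240 features passed, 2098 in the same direction (1112 higher, 986 lower) and 142 in opposite directions. Independent lists of these sizes would share 256 higher and 262.7 lower features. The 100 simulated pairs of unchanged groups, each pair with a shared simulated control, shared 0. That 0 says little, since unchanged groups yield few calls at an adjusted threshold. Log2 differences correlated across features with r = 0.554, against a mean of 0.501 in the simulated pairs, and their covariance was 0.0490 against 0.00614, a difference of 0.0429. With 3 control arrays the controls cannot be divided into 2 sets of at least 2, so part of the excess may come from the shared controls. The simulation also gave the controls the pooled spread, although control replicates 1 and 2 varied more than the other arrays. Of the features called for miR-376a*A only, 1017 of 1937 also passed between the forms, as did 1370 of the 2753 called for miR-376a*G only and 400 of the 2098 called in the same direction. The 142 opposite calls comprised 84 higher with miR-376a*A and lower with miR-376a*G and 58 of the reverse, against 282.4 and 238.1 for independent lists. RASSF3 fell by 1.05 ± 0.123 with miR-376a*A and rose by 1.02 ± 0.123 (log2, SE) with miR-376a*G. RRM2B rose by 0.56 ± 0.125 with miR-376a*A and fell by 0.75 ± 0.125 with miR-376a*G. Further opposite genes, named after their values were seen, were the pseudophosphatase gene STYX (-0.78 ± 0.109 and 0.79 ± 0.109), the cytokine receptor gene LIFR (0.89 ± 0.087 and -0.45 ± 0.087) and HIVEP3 (0.96 ± 0.116 and -0.60 ± 0.116). With miR-376a*A, 2 of 4 other tested probe sets of LIFR (lowest -0.09) and 1 of 2 of RASSF3 (highest 0.06) shared the sign. With miR-376a*G, 1 of 2 of STYX did (lowest -0.003). With the other form all others of these 3 genes shared the sign, and 0 passed in the opposite direction.

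Markers of other cell types stayed dim. The 5 tested epithelial markers had a median signal of 16.6 and the 6 tested blood cell markers one of 31.9, against 77.8 over all tested features. No epithelial marker passed in any comparison. Among blood cell markers CSF1R was higher with miR-376a*A and CD3E lower with miR-376a*G than in the control, and both were higher with miR-376a*A than with miR-376a*G. The CD3E calls each ended without several single arrays, with adjusted p between 0.0543 and 0.153. Only 3 endothelial markers were bright enough to be tested, at a median signal of 46.1 and too few for a list test. PECAM1 and TEK were higher with miR-376a*A and KDR and TEK with miR-376a*G than in the control, and PECAM1 was higher with miR-376a*A than with miR-376a*G. The endothelial genes were named after their values were seen. The TEK call with miR-376a*A ended without replicate 1 or 3 of that group (adjusted p = 0.0574 and 0.0583). The KDR call ended without miR-376a*G replicate 1 or 3 or control replicate 2 and without the filter on dim probe sets, with adjusted p between 0.0606 and 0.124. With miR-376a*A, KDR passed only with the replicate number as a block (adjusted p = 0.0281) or without miR-376a*A replicate 2 (adjusted p = 0.022). TEK was not called between the forms (adjusted p = 0.0519). It passed as lower with miR-376a*A in 6 alternatives, array weights among them, with adjusted p between 0.0145 and 0.0496. Among 15 tested glial and neural lineage genes 2 rose and 1 fell with miR-376a*A and 1 rose and 3 fell with miR-376a*G, and between the forms 1 was higher and 1 lower. None of the epithelial, blood cell and glial lists was called, with camera adjusted p from 0.168 to 0.902.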

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

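Among the tests below, that of control replicate 1 on the ribosomal protein genes and that of control replicate 1 on the G2/M genes were chosen only after the result was seen.

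The forms differed from each other in the direction of single genes. Against the shared control, 84 features were higher with miR-376a*A and lower with miR-376a*G and 58 were the reverse. The difference between the forms is then the sum of both changes at the same SE, so their passing the direct comparison adds no evidence. The direct comparison also set lists apart. With miR-376a*A minus miR-376a*G, the median log2 difference was -0.38 for NF-kB and inflammatory cytokine genes, -0.12 for G1/S and DNA replication genes and -0.24 for G2/M and mitosis genes. It was 0.14 for p53 target genes, 0.35 for integrin and focal adhesion genes, 0.25 for hypoxia and glycolysis genes and -0.29 for replication-dependent histone genes. Of these lists, G2/M and mitosis genes alone kept their call with an estimated correlation (adjusted p = 0.0185).

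G2/M and mitosis genes were higher with miR-376a*G than in the control, with a median of 0.27. The scaling between arrays and control replicate 1 are argued against as whole causes, since the median was 0.24 after quantile normalization and 0.28 without that array. The brightness of the list's genes is argued against too, because the median lay at percentile 100 of 10000 random lists matched on mean expression, whose highest median was 0.247. An effect of the edited form on cycling cells stays open as a hypothesis, and no cell numbers or cycle phases were analysed here.

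Cytosolic ribosomal protein genes were higher with miR-376a*A than in the control by a median of 0.13, although 0 of 26 passed singly at an adjusted p under 0.05 in limma and 10 did without control replicate 2. The median was 0.031 after quantile normalization (adjusted p = 0.651), whereas the call held after median centring (median 0.093, camera adjusted p = 0.017). The scaling between arrays is therefore not excluded. With only replicates 2 and 3 of every group, which leaves out miR-376a*A replicate 1 too, the median was 0.027. Without control replicate 1 alone it was 0.076 with an adjusted p of 0.246. With as many arrays it was 0.184 without control replicate 2 and 0.13 without control replicate 3, so a smaller number of arrays alone does not account for the fall. The estimated correlation among these genes was 0.846, so they act as little more than a single measurement. The list's mean deviation from the average of all arrays was 0.15, 0.05 and 0.02 (log2) on miR-376a*A replicates 1, 2 and 3. On control replicates 1, 2 and 3 it was -0.18, 0.08 and -0.07. The scaling, control replicate 1, miR-376a*A replicate 1 and an effect of miR-376a*A cannot be told apart here.

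The 6 arrays of each comparison can be split into groups of 3 in 10 ways, which cannot give a share under 0.05 (the smallest is 0.1). In fits of the 2 groups alone, the real split gave 3191 features for miR-376a*A against control, 4021 for miR-376a*G against control and 5472 between the forms. The highest other split gave 0 each time, so 1 of the 10 splits reached the real count. Every other split mixes arrays of both groups, so the real differences enlarge its spread and a low count follows. For gene lists the real split gave 3, 6 and 8 called lists and the highest other splits 4, 5 and 7. For miR-376a*A against control 2 of the 10 splits gave at least as many lists as the real one, and 1 of 10 did in the other comparisons. Counts of lists called by camera are therefore not set apart by these splits. As the mixed splits keep part of the real difference, they do not show how many lists would be called without one.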

How the results depend on the processing

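The alternative that kept only replicates 2 and 3 of every group was chosen after seeing the data, and all others before. Of 165 named gene results that passed, 155 kept their direction and their side of the threshold in every alternative run and 0 reversed. Most of these genes were named for large differences or small p in these same arrays, so a kept call was likely. Their share does not carry over to all called features. Over all 2310 alternative values of these genes, 40 no longer passed. The 16 called lists kept their call in 182 of 208 alternative values. Interferon-stimulated genes and ribosomal protein genes apart, they lost it only with an estimated correlation. That setting left 0, 1 and 1 called lists for miR-376a*A against control, miR-376a*G against control and between the forms, while fry, which tests another hypothesis, called 8 and 11 against the control. With miR-376a*A, 1 list was called after quantile normalization, and 1 with only replicates 2 and 3. Leaving out each replicate in turn gave 1 to 4 lists there, with 1 without miR-376a*A replicate 1. The cause was not tested.

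Array weights gave 8926, 9466 and 6354 features in the 3 comparisons, but they gave control replicate 3 a weight of 8.156 against 0.189 for control replicate 1 and their estimation did not converge to its tolerance, so these counts carry little weight. A change of at least 1.5-fold was passed by 872, 1120 and 878 features, by construction fewer. Between the forms, leaving out each replicate gave 2331 to 2960 features, with fewer arrays in the fit, and the lowest counts, 2331 and 2441, came without miR-376a*G replicate 2 and miR-376a*A replicate 2. Without control replicate 1, 4532 and 5320 features passed against the control and 2303 in both with the same direction. With only replicates 2 and 3 the counts were 3992, 5015 and 4123. For miR-376a*A against control, 2985, 2829 and 2838 features passed without miR-376a*A replicate 1, 2 or 3, against 4177 with all arrays. The other alternatives stayed within 1.5 times of the reported counts.

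Arrays of the same replicate number did not deviate together: the 9 correlations lay between -0.11 and 0.071, and 3 of 9 arrays correlated best with an array of their own number. With the replicate number as a block 3840, 4714 and 3325 features passed, 1931 of them in both comparisons with the control and in the same direction, and the block changed no list call. The comparison of genes with seed sites and its alternatives were not run, and the endothelial and study target lists held too few tested genes for a list test. Signal over background limits the dim genes, whose folds the offset shrinks.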

Other observations

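The gene families described here and the shares of group-specific features that were lower were chosen only after the result was seen.

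Genes of the mitochondrial ribosome were higher with miR-376a*G. Among 80 families of at least 15 tested genes formed from the stems of gene symbols, those of the large subunit (MRPL) had 22 of 49 genes higher and 1 lower than in the control, with a median of 0.29 and a camera adjusted p of 9.78e-08. The small subunit (MRPS) had 18 of 27 higher and 0 lower, with a median of 0.33 and the same adjusted p. With an estimated correlation the adjusted p was 0.804 and 0.779, and without control replicate 1 the medians were 0.15 and 0.22. MRPS14 rose by 1.88 ± 0.105 (log2, SE), MRPL35 by 0.84 ± 0.109 and MRPL1 by 0.74 ± 0.084, whereas MRPL43 fell by 0.59 ± 0.098. MRPS14 rose as much with miR-376a*A, by 1.90, so its rise was not particular to miR-376a*G. With miR-376a*A these families were not called (medians 0.19 and 0.13, adjusted p = 0.065 and 0.193), and without control replicate 1 the medians were 0.025 and 0.005. Between the forms the families were called as lower with miR-376a*A (medians -0.13 and -0.17, adjusted p = 0.00162 and 0.0011), with adjusted p of 0.776 and 0.769 with an estimated correlation. Only 4 of 49 and 6 of 27 genes were lower there, and 1 and 0 higher, whereas 18 and 15 were lower without control replicate 1. Histone lysine demethylase genes (KDM) fell in 9 of 18 cases with miR-376a*G and rose in 0 (median -0.28, adjusted p = 0.0174), among them KDM5B at -0.97 ± 0.114 and KDM4B at -0.72 ± 0.102 (SE). Their adjusted p was 0.779 with an estimated correlation and 0.0501 after quantile normalization, the median was -0.18 without control replicate 1, and between the forms the family was not called (adjusted p = 0.167).

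Some features were at least 2-fold lower in the control transfection than with either form, 45 against 16 that were at least 2-fold higher there. The 45 include NUP37, ATL3, GALNT1, GLO1, IL6, CXCL3 and CCNA2, and most of the largest rises named above for either form. With miR-376a*A and miR-376a*G, ATL3 rose by 2.20 and 2.19 (log2), GALNT1 by 2.09 and 2.07 and GLO1 by 1.97 and 2.04. TMEM106B was less even, at 1.11 and 2.09. Control replicate 1 and the scaling between arrays are argued against as whole causes, since 50 such features were found without that array and 50 after quantile normalization. Whether each duplex, the control included, lowers a set of genes of its own or both forms raise these genes stays open. Of the features at least 2-fold apart from both other groups, 73.8% were lower in the control, 89.3% (67 against 8) with miR-376a*A and 86.7% (65 against 10) with miR-376a*G. The control's share restates the pattern, and the other shares do not tell the explanations apart. No untransfected cells were analysed here.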
